A study of Arabidopsis thaliana with 30 samples.

How the data were processed

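RNA was measured by sequencing of ribosome-depleted, strand-specific libraries from detached leaves of Arabidopsis thaliana seedlings. The labels define 10 groups: mock or stimulus at 6, 7, 8, 9 and 10 h, with 3 biological replicates each, 30 libraries in all. A 5 h time point named in the design text was not analysed here. The authors deposited raw counts per gene locus, 38194 loci by 30 libraries, per the file headers. Per the submitters' processing notes, BWA and the TAIR10 build were used, without stated versions or roles. The counting tool and annotation are not given in the sources used here.

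Of the 38194 loci, 37751 were paired by AGI locus with records of the TAIR10.1 assembly, whose build name differs from the one in the notes. Gene names were taken from it and no coordinates are printed. Counting appeared to use strand: where 1 locus lies within another, the outer locus held at least as many counts as the inner one in all libraries for 55 of 57 pairs on the same strand and for 9 of 86 on opposite strands. Overlapping loci on the same strand share reads, so their values are uncertain.

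Library totals ranged from 14981271 to 22729166 counts (19215617 ± 1930409, SD, n = 29 distinct libraries), of which 12175574 ± 1343124 fell on nuclear loci other than rRNA and tRNA genes. The mock 6 h replicate 3 and mock 7 h replicate 3 columns were identical at every locus, the only such pair among 435. In any other pair at most 3.65% of the loci with a count in either library had equal counts. The 30 columns therefore hold 29 distinct libraries, 14 of them mock, and which of the 2 labels is right is not known. They were counted once in means and SDs. Because they carry labels of different groups, fits were made as designed with all 30 columns, and again without both copies.

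The counts were tested with edgeR 4.0.16 in R 4.3.3. Loci were filtered with filterByExpr, which left 21052 genes, and scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 30 libraries. Contrasts were stimulus minus mock at each time, their average over the 5 times, the treatment by time interaction on 4 degrees of freedom, and linear trends per hour in mock, in stimulus and in their difference. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors were derived from the log2 fold change and its F statistic. The labels do not say whether replicates came from separate batches of plants, so p-values measure the spread between these samples.

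Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and again with an estimated one. There were 20 lists fixed by name, with 300 members, and 2 lists defined by a rule, for cytosolic ribosomal proteins and core histones. The ribosomal list was changed after its values had been seen. Its rule excluded organellar proteins, but the first matching, of 44 loci, had taken in several whose product names no compartment. It was narrowed to the 30 loci that the annotation places in the cytosol or names as 40S or 60S, which also dropped a few cytosolic proteins with no stated compartment. Values of both versions are given. The lists and the choices of tests were otherwise fixed before the data were examined. A count of 5 or fewer genes outside the naming rule is named as chosen afterwards.

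Named genes followed a fixed rule: the 10 largest and 10 smallest average log2 fold changes among genes past the threshold with 1 sign at all 5 times and a mean log2 CPM of at least 1, up to 2 genes each way per list, up to 10 each way for the difference of trends, 5 each way for the mock trend, and up to 5 for the interaction with opposite effects at 2 times.

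Replicate numbers were checked for pairing. Deviations from group means correlated above 0.1 in 15 of 15 mock and stimulus pairs of the same number and time (0.158 to 0.486). Replicate 3 stood apart in every group, so such correlations can arise for replicates 1 and 2 whatever their number. Only 9 of the 15 stimulus libraries correlated best with the mock library of their own number, among them replicate 3 at every time. Pairing of replicates 1 and 2 by number was therefore not shown. The numbers were still treated as pairs, and fits with the number as a block are given where they change a call. Alternatives were DESeq2 1.42.0, DESeq2 size factors, other count filters, removal of organelle, rRNA and tRNA loci, a replicate block, each library left out, fewer libraries or times, and other models of time. Fits without the identical columns, within replicate subsets and on counts summed over times were added after the data were seen. On simulated data with 200 changed genes, the average contrast recovered 86% of genes with a log2 change of 1 and 100% with 2, and a single time 36% and 88%, among 20836 genes. For trends that differed by 0.25 and 0.5 per hour, the difference of trends recovered 17% and 69% of genes and the interaction 3% and 40%, among 20825 genes. The simulated spread was taken from the data, but counts were drawn independently around 1 mean per gene. They held no shared offset or differing response of replicate 3 and no identical columns. Recovery in the real data may therefore differ from these rates.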

Results

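The series followed RNA abundance over time in detached leaves, to obtain rates of change for comparison with rates of RNA decay. Leaves 1 and 2 of 10 d old Arabidopsis seedlings were kept in buffer with 5% glucose and 0.2% DMSO. The stimulus, a treatment that turns leaf cells toward vascular fates, added 20 µM bikinin, an inhibitor of GSK3 kinases that activates brassinosteroid signalling, 2.5 µg/mL of the auxin 2,4-D and 0.5 µg/mL of the cytokinin kinetin. Mock and stimulus were each sampled at 6, 7, 8, 9 and 10 h with 3 replicates. Libraries held 14981271 to 22729166 counts, and mitochondrial loci took 34.4 ± 1.99% of them (SD, n = 29). Of the 30 libraries 29 were distinct, since replicate 3 of mock at 6 h and at 7 h held identical counts, and these were counted once in means.

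Treatment and replicate number both separated the libraries. The first principal component held 45.2% of the variance and the second 24%. Replicate 3 of every group stood apart from replicates 1 and 2. Plastid loci took 0.692 ± 0.115% of counts in the 9 distinct replicate 3 libraries and 2.38 ± 0.488% in the 20 others, and nuclear rRNA and tRNA loci 0.0636 ± 0.0252% and 0.480 ± 0.191% (SD). Organelle rRNA and tRNA loci are counted with the plastid and mitochondrial loci. The labels name no batch. Values within these sets are therefore given beside the main results for some lists and genes.

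**Figure D1:**
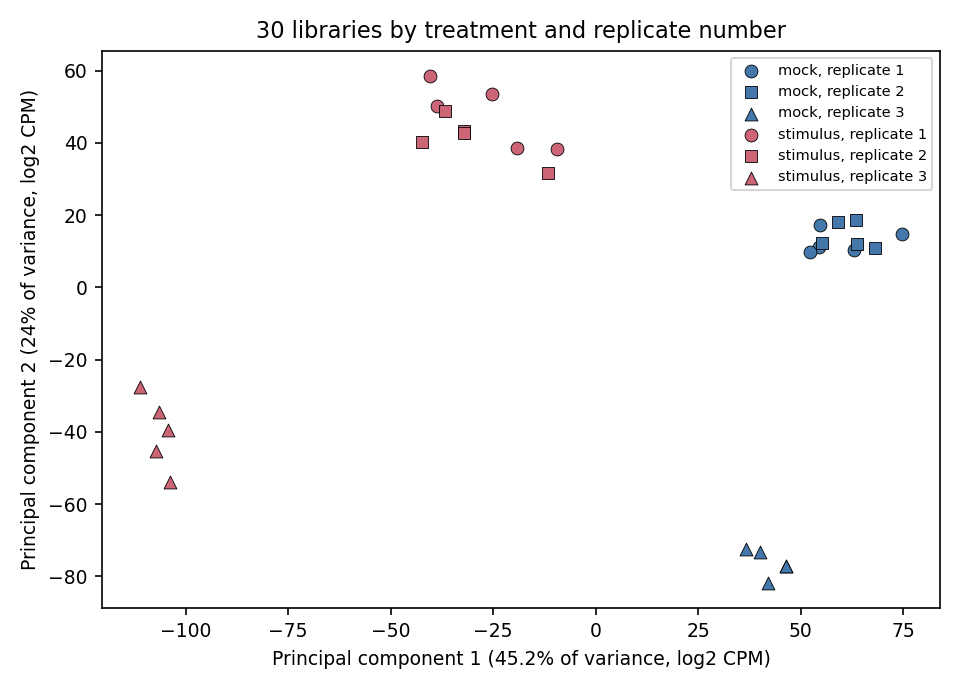
The first 2 principal components of log2 CPM for the 30 libraries, coloured by treatment and shaped by replicate number. Replicate 3 libraries lie below replicates 1 and 2 within each treatment, and 2 mock replicate 3 points coincide because their counts are identical.

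The first question was which genes the stimulus changed on average over the 5 times. Of 24 auxin-induced genes 23 were higher, among them GH3.3. GH3.3 (AT2G23170), which conjugates auxin to amino acids, went from 2.33 ± 1.61 to 1096 ± 104 CPM (SD, 14 distinct mock and 15 stimulus libraries). Of 14 jasmonate and wound response genes 12 were lower. VSP2 (AT5G24770), a vegetative storage protein, went from 80.6 ± 37.6 to 1.56 ± 2.74 CPM. By edgeR, 6250 genes were higher and 5677 lower among 21052 tested, 1610 and 1579 of them by more than 2-fold. This fit, its SEs and the list tests below took the 5 times of each replicate number as separate libraries, although replicate 3 stood apart at every time. Their p-values therefore do not measure spread between independent replicate sets. Counts summed over times, which leave 3 mock and 3 stimulus sums, gave 1014 genes higher and 810 lower among 22217 tested.

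Among the largest rises, GH3.3 had a log2 fold change of 8.97 ± 0.44 (SE), GH3.2 (AT4G37390) 8.89 ± 0.31, and the ethylene biosynthesis genes ACS4 (AT2G22810) and ACS5 (AT5G65800) 8.70 ± 0.27 and 7.97 ± 0.31. AT5G62280, AT5G66940 (a Dof-type zinc finger protein), GH3.1, SAUR28 and ROXY2 rose by between 6.42 and 7.99. Each of these 9 genes was higher in 15 of 15 same-numbered pairs, where the replicate 3 pairs at 6 h and at 7 h share 1 mock library. BCA3 (AT1G23730), a carbonic anhydrase, averaged 6.68 ± 1.34, with 0.97 in replicates 1 and 2 and 7.40 in replicate 3. The largest falls were VSP2 at -6.06 ± 0.46, VSP1 at -5.38 ± 0.70, AT5G57785, the thionin gene THI2.1, AT5G22580, MBP2, EPF2, ORA47, CYP710A2 and CSLA01, the last at -4.36 ± 0.30. Some of these varied widely among mock libraries. In mock at 9 h THI2.1 stood at 19.1 ± 17.4 CPM, VSP1 at 29.4 ± 24.4 and ORA47 at 11.9 ± 10.5 (SD, n = 3). THI2.1 was far lower in replicate 3 of mock than in replicates 1 and 2. Falls within the replicate sets are not given for these genes.

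Of 24 auxin-induced genes tested 23 rose and none fell, with a median log2 fold change of 3.33 (limma camera adjusted p = 2.12e-16). Of 17 cytokinin response genes 14 rose, led by CKX3 at 5.58 ± 0.30, which degrades cytokinin, and ARR5 at 5.32 ± 0.41, a type-A response regulator (camera adjusted p = 2.18e-08). Of 9 brassinosteroid-induced growth genes 8 rose, including BEE1 at 4.91 ± 0.46, and XTH22 fell by 1.69 ± 0.22 (camera adjusted p = 1.46e-05). These 3 lists held with an estimated correlation, each at an adjusted p of 0.0134. Of 10 brassinosteroid biosynthesis genes 9 fell, among them ROT3 at -3.50 ± 0.43 and BR6OX2 at -3.37 ± 0.52 (camera adjusted p = 0.000171). That call was lost with an estimated correlation (adjusted p = 0.112), and on counts summed over times 0 of the 10 passed. The median of that list was -1.97 in replicates 1 and 2 and -4.84 in replicate 3.

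Vascular genes responded unevenly. Of 19 procambium and cambium genes 12 rose and LHW fell, with LOG3 at 5.40 ± 0.41, an enzyme that activates cytokinin, and TMO6 at 3.24 ± 0.08 (camera adjusted p = 5.52e-06, and adjusted p = 0.174 with an estimated correlation). Of 15 phloem genes 7 rose, including BRX at 2.67 ± 0.14, and FTIP1 fell (camera adjusted p = 0.00134, and 0.0134 with an estimated correlation). Among 19 xylem genes 4 rose, including VND2 at 1.60 ± 0.14 and VND1 at 1.34 ± 0.13, regulators of vessel formation, and 6 fell, including VND6 at -0.87 ± 0.23 (camera adjusted p = 0.597). CESA4, at -0.65 ± 0.08, overlaps a locus with more counts on the same strand and is uncertain.

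Of 38 core histone genes 31 rose and HTA12 fell, with RAT5 at 1.75 ± 0.09 (camera adjusted p = 2.12e-16, and 0.0344 with an estimated correlation). Of 22 cell cycle and DNA replication genes 14 rose, including CYCD6;1 at 1.63 ± 0.23 and PCNA1 at 1.14 ± 0.11, and 3 fell, including CYCD1;1 (camera adjusted p = 0.000129, and adjusted p = 0.295 with an estimated correlation). Of 26 cytosolic ribosomal protein genes 18 rose and none fell (camera adjusted p = 0.000333, and adjusted p = 0.412 with an estimated correlation). This list was narrowed after its values had been seen. On counts summed over times 0 of the 26 passed. As first matched, with organellar proteins among its members, 23 of 40 rose and 7 fell (camera adjusted p = 0.0127, and adjusted p = 0.649 with an estimated correlation), and all 7 that fell were among the 14 tested genes removed. The median of the narrowed list was 0.61 in replicates 1 and 2 and 0.17 in replicate 3.

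All 38 nuclear photosynthesis genes tested fell in the fit of all libraries, and 7 on counts summed over times, with LHCB2.3 at -3.17 ± 0.48 and RBCS2B at -1.73 ± 0.15 (camera adjusted p = 3.91e-10, and adjusted p = 0.3 with an estimated correlation). Their median was -0.61 in replicates 1 and 2 and -1.70 in replicate 3. Of 14 jasmonate and wound response genes 12 fell (camera adjusted p = 4.61e-07, and adjusted p = 0.106 with an estimated correlation). Of 9 stomatal lineage and guard cell genes 6 fell, with EPF2, which limits stomatal number, at -4.65 ± 0.35 and TMM at -1.86 ± 0.13 (camera adjusted p = 0.000635, and adjusted p = 0.106 with an estimated correlation).

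All 5 xenobiotic detoxification genes rose, including the glutathione transferase gene GSTU25 at 2.58 ± 0.33 (camera adjusted p = 0.00241, and adjusted p = 0.223 with an estimated correlation). Of 5 ethylene response genes 3 rose, with ERF1 at 2.55 ± 0.25 (camera adjusted p = 0.00699, and adjusted p = 0.203 with an estimated correlation). Of 31 mRNA decay genes 12 rose, including RRP4 at 0.85 ± 0.11, and 3 fell, among them the deadenylase genes CAF1B at -1.91 ± 0.23 and CAF1A at -1.60 ± 0.20 (camera adjusted p = 0.0768). Of 10 abscisic acid genes 2 rose and 1 fell (camera adjusted p = 0.49), of 12 clock genes 2 fell (0.46), of 6 epidermis genes 1 rose and 3 fell (0.336), of 3 trichome genes 2 fell (0.344), and of 7 root and callus genes 4 rose, led by WOX11, and 2 fell (0.371). Of 7 sugar starvation genes 3 rose and 2 fell (camera adjusted p = 0.527), with a median of -0.63, a mean of 0.82 and TPS11 at 3.95 ± 0.17.

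Adjusted over the list alone, 15 higher were counted for cytokinin, 15 for cell cycle, 20 for ribosomal protein and 32 for histone genes, 7 lower for xylem and 1 lower for clock genes, and 1 brassinosteroid biosynthesis gene was higher. The other lists gave the counts above. With replicate number as a block, higher and lower genes numbered 5 and 2 for abscisic acid, 5 and 0 for ethylene, 3 and 4 for sugar starvation, 1 and 4 for clock, 1 and 5 for epidermis, 5 and 2 for root and callus, 24 and 0 for ribosomal protein and 9 and 1 for phloem genes. They numbered 15 and 0 for cytokinin, 1 and 9 for brassinosteroid biosynthesis, 13 and 1 for procambium, 4 and 7 for xylem, 15 and 3 for cell cycle, 14 and 4 for mRNA decay, 0 and 13 for jasmonate and 31 and 2 for histone genes, and the remaining lists had the counts of the unblocked fit. In replicates 1 and 2 and in replicate 3 the medians were 3.45 and 2.02 for cytokinin, -2.0 and -1.23 for jasmonate, 1.22 and 3.37 for xenobiotic and 1.3 and 0.39 for ethylene genes. By camera 14 lists passed on average, 5 with an estimated correlation, and exchanges of mock and stimulus within some of the 15 pairs gave up to 15.

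**Figure D2:**
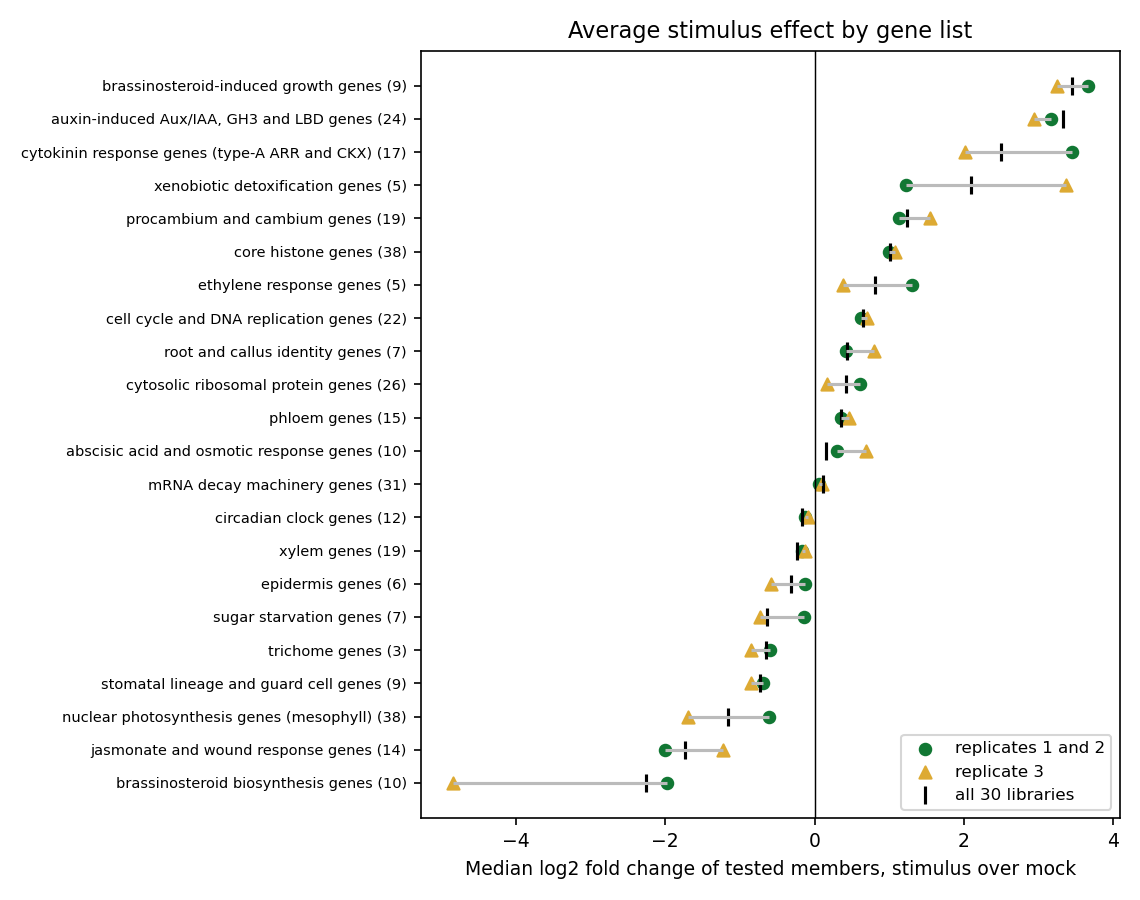
Median log2 fold change, stimulus over mock, of the tested members of each list (number in brackets) in replicates 1 and 2, in replicate 3 and in all 30 libraries. Auxin-induced genes have medians of 3.16 and 2.94 in the 2 sets, and brassinosteroid biosynthesis genes -1.97 and -4.84.

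Of the 11927 genes called, 11467 had the same sign in replicates 1 and 2 as in replicate 3, and 8765 were called in both sets with 1 sign. These genes were selected on the average of both sets, which favours a shared sign. Over all 21052 genes tested 75.4% had the same sign, with a Pearson r of 0.698 across genes. The response itself differed between the sets for 10361 genes by edgeR, with the 5 times of 1 replicate number taken as separate libraries. The p-values behind this count do not measure spread between independent replicate sets, of which replicate 3 is 1. Counts summed over times, which leave 3 mock and 3 stimulus sums, gave 1824 genes, and 3653 with a replicate block. On these sums 17 auxin, 7 cytokinin, 7 brassinosteroid-induced growth, 10 procambium, 5 phloem, 3 xylem, 8 cell cycle, 23 histone, 2 ethylene, 2 sugar starvation, 1 xenobiotic, 1 abscisic acid, 1 epidermis and 1 root and callus gene were higher. Lower were 7 photosynthesis, 7 jasmonate, 3 stomatal, 2 mRNA decay and 1 brassinosteroid-induced growth gene, and the lists for brassinosteroid biosynthesis, ribosomal proteins, the clock and trichomes had 0 either way.

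The next comparisons asked which genes differed at each time. GH3.3, chosen among genes with 1 sign at all 5 times, had a log2 fold change of 9.15 at 6 h and 8.46 at 10 h, and VSP2, chosen likewise, -6.37 and -5.76. By edgeR, 1270 genes were higher and 808 lower at 6 h, 1873 and 1714 at 7 h, 1376 and 1346 at 8 h, 1677 and 1800 at 9 h, and 2050 and 1967 at 10 h. At all 5 times 734 genes were higher and 544 lower, and 3 genes were higher at 1 time and lower at another. Across genes, which are not independent replicates, fold changes at 2 times had a Pearson r between 0.808 and 0.906, and the 6 and 7 h values share an identical mock library. With replicate number as a block the totals were 6395, 7970, 6977, 7818 and 8318 genes from 6 to 10 h. Fitted on only the 6 libraries of each time, the totals were 278, 1695, 713, 1449 and 1867. In fits that each left out 1 library, replicate 3 of the stimulus at the time tested, they were 851, 2240, 1575, 2103 and 2566, and in replicates 1 and 2 only 6259, 8002, 7374, 7945 and 8260.

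**Figure D3:**
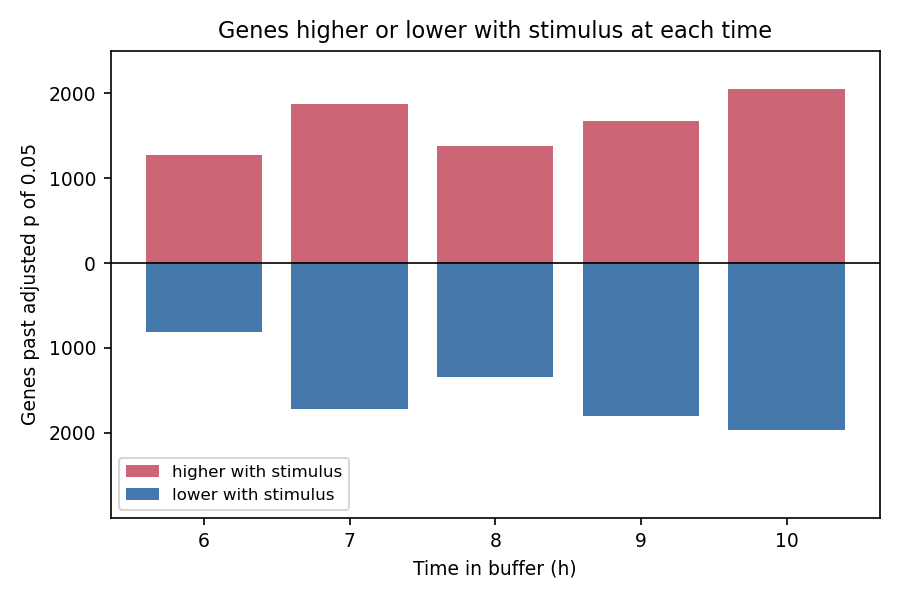
Genes past an adjusted p of 0.05 in edgeR at each time in hours, with genes higher with the stimulus drawn upward and lower ones downward. The bars run from 1270 up and 808 down at 6 h to 2050 up and 1967 down at 10 h.

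Whether the hourly change differed between stimulus and mock was tested next. By edgeR 4 genes passed, all with the higher slope in the stimulus. AT5G42720, a glycosyl hydrolase family 17 gene, changed by 0.33 ± 0.05 log2 per hour more than in mock (SE, adjusted p = 0.00685), and AT4G02800, a coiled-coil protein gene, by 0.43 ± 0.07 (adjusted p = 0.0286). AT5G36710 and AT5G36800, which lie below the level limit for named genes and were chosen after their values were seen, differed by 0.52 ± 0.09 and 0.55 ± 0.09. These 2 loci share 97.2% of 31-base words and their reads may not be separable. With a replicate block 262 genes passed, without the identical mock libraries 94, and without stimulus 10 h replicate 3 50. Without each of 15 other libraries 1 gene passed, without the 6 h or the 10 h libraries 0, and in replicates 1 and 2 only 684 had the higher slope in the stimulus and 940 the lower.

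The stimulus effect differed between times for no gene by the edgeR interaction test, against 15 genes by DESeq2 and 93 with a replicate block. In a fit of replicates 1 and 2 alone, 596 genes passed. In the main test 336 of 21052 genes had an unadjusted p under 0.05, fewer than a share of 0.05. The test was thus conservative here, and its count of 0 is weak evidence that no effect differed. KN (AT1G08560), a syntaxin gene of cytokinesis, was the only gene with opposite effects past the threshold at 2 times and a sufficient level, lower at 7 h (edgeR adjusted p = 0.00832) and higher by 1.09 ± 0.25 at 10 h (adjusted p = 0.00415), with an interaction adjusted p of 0.511. By camera the difference of slopes, stimulus minus mock, was shifted upward in the procambium list (adjusted p = 2.45e-05) and in sugar starvation genes (adjusted p = 0.0157) and downward in stomatal genes (adjusted p = 0.0467), although 0 of their 19, 7 and 9 members passed singly over all genes. With an estimated correlation each of these 3 lists had a camera adjusted p of 0.498. With a replicate block the procambium list alone passed (camera adjusted p = 5.94e-11). Adjusted over the list alone, 1 procambium and 1 sugar starvation gene had the higher slope in the stimulus. Among cell cycle genes 5 had the higher and 5 the lower, and 1 trichome gene had the lower. With a replicate block the higher slope was in the stimulus for 3 procambium, 1 sugar starvation, 1 phloem and 5 cell cycle genes, and the lower for 2 cell cycle genes.

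**Figure D4:**
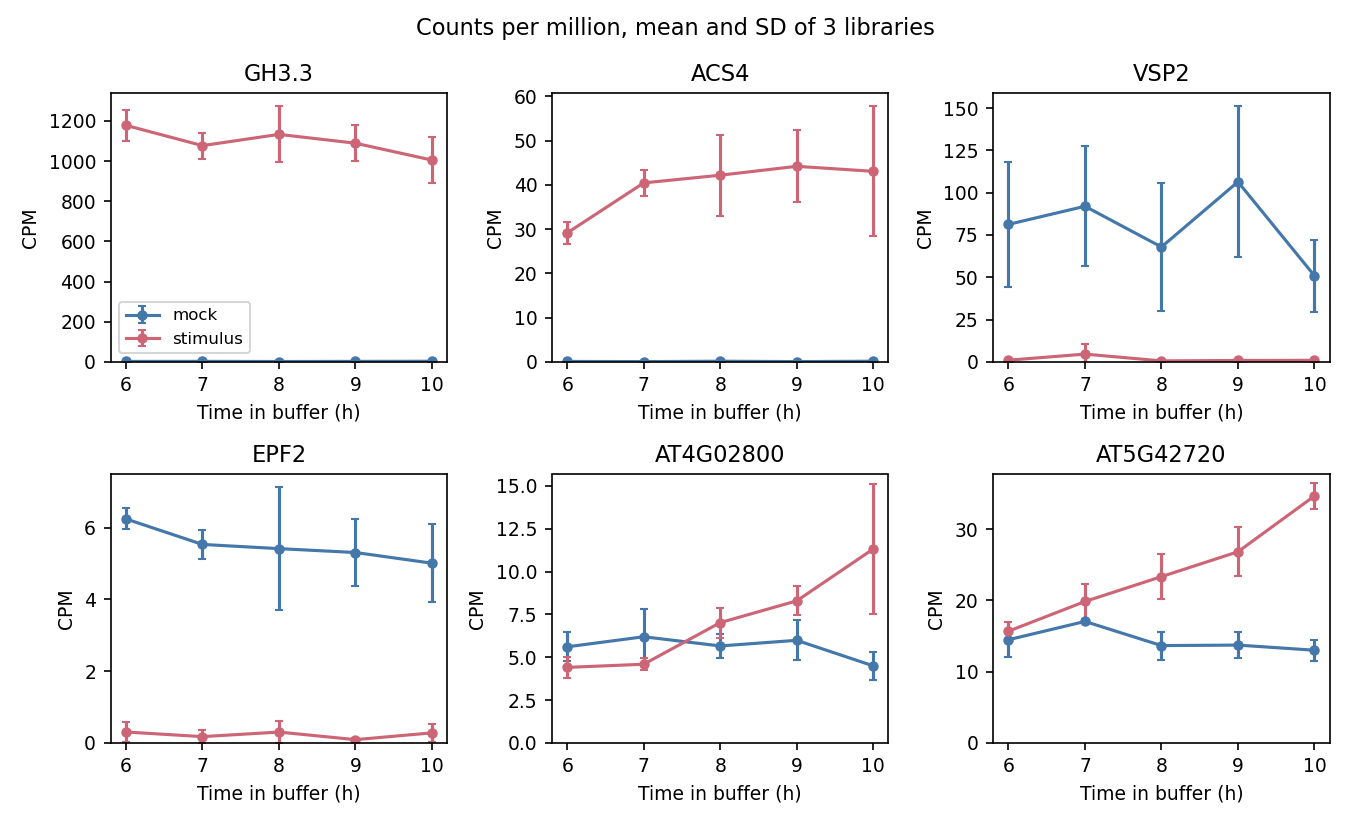
CPM (mean and SD of 3 libraries) against time in hours in mock and stimulus for 6 named genes, where the 6 h and 7 h mock groups share 1 identical library. GH3.3 and ACS4 lie higher and VSP2 and EPF2 lower with the stimulus, and AT4G02800 and AT5G42720 rise with time in the stimulus.

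Drift in mock leaves gave the background for these trends. PIF4, a transcription factor of growth, and the clock genes GI and PRR7 fell by 0.63 ± 0.15, 0.60 ± 0.11 and 0.56 ± 0.11 log2 per hour, as did AT5G51950 and AN3. AT3G04210 rose by 0.66 ± 0.14 per hour, with AT5G24210, ERD6, CNGC11 and TRX1 also rising, although TRX1 overlaps a locus with more counts on its strand. By edgeR 63 genes rose and 89 fell in mock, and 169 rose and 45 fell in the stimulus. With a replicate block 807 and 1342 genes passed, and without the identical libraries 285 passed in mock. Without the 6 h libraries 13 genes passed in mock and 4 in the stimulus, and without the 10 h libraries 14 and 12. Leaving out 1 library gave as few as 52 in mock, without mock 10 h replicate 1, and 55 in the stimulus, without stimulus 10 h replicate 2, and in replicates 1 and 2 only 2379 rose and 2424 fell in mock and 1462 rose and 2033 fell in the stimulus.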

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

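The comparison of replicate 3 with replicates 1 and 2, and the tests on it, were chosen after the data were seen, and the test of opposite signs after its value was known. For 10361 genes the average response differed between the 2 sets, with the 5 times of 1 replicate number taken as separate libraries. The p-values behind that count do not measure spread between independent replicate sets. Among genes chosen after their values were seen, PAD3, of camalexin synthesis, stood at 5.51 in replicate 3 against 0.78 and BR6OX2 at -8.96 against -2.85. Among 100 choices of 1 library per group, 1 gave as many genes, the real one, and the highest other, 9228, included replicate 3 in 6 of the 10 groups. Replicate 3 was picked because it stood apart, and most other choices leave its offset in the spread. The ranking was therefore set beforehand and decides nothing. A response of 1 shape but larger size is argued against as the whole difference by opposite signs in 8.78% of the 10243 genes called in both sets. The other 9344 had the same sign, and 75.8% of them responded more in replicate 3. The SD of log2 fold changes was 1.28 in replicate 3 and 0.819 in replicates 1 and 2, so a larger size may be part of it. Replicate 3 has fewer libraries per group, so noise may also widen its SD and raise the share of 75.8%. The regression slope of replicate 3 on replicates 1 and 2 across genes was 1.09. Unequal depth is argued against because thinning every library to the lowest nuclear total left 96.2% as many genes. A difference in plants or handling may remain, and no biological explanation was tested for the difference in response, since the labels name none.

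Hourly changes in the stimulus minus mock passed for AT4G02800 (0.426 log2 per hour), AT5G42720 (0.335), AT5G36710 (0.517) and AT5G36800 (0.551). As lists, procambium genes (adjusted p = 2.45e-05), sugar starvation genes (0.0157) and stomatal lineage genes (0.0467) differed by limma camera. With an estimated correlation each had an adjusted p of 0.498, and with a replicate block sugar starvation genes had an adjusted p of 0.0798 and stomatal genes 0.0908. Groups of 3 libraries were not tested for single outlying values.

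Few hourly trends passed with replicate 3 in the fit: 214 genes in the stimulus, against 3495 in replicates 1 and 2 alone. A candidate explanation is an offset of replicate 3 with the same time course. With such offsets removed by a block within each treatment, 3190 genes passed in the stimulus and 2887 in mock. Over the 3489 genes with a stimulus trend in replicates 1 and 2 that were also tested in all libraries, the stimulus slopes in replicate 3 had a Pearson r of 0.393 with the others (same sign in 67.0%), and over the 4797 such genes in mock the r was 0.269 (54.8%). The stimulus value lies between the bounds set for and against a shared time course, so this part stays open, and genes are not independent.

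The counts of genes were compared with other groupings of the same libraries. At each single time 1 of the 10 splits, the real one, called 2078, 3587, 2722, 3477 and 4017 genes from 6 to 10 h, and the highest other split 0, but 10 splits are too few for a share under 0.05. The 3 other splits that also part all 3 same-numbered pairs called 0 genes at each time. Every split but the real one mixes mock and stimulus libraries within a group, so a stimulus effect enlarges its spread. These counts of 0 are therefore no measure of false calls in the real split. Of 100 exchanges of mock and stimulus within same-numbered pairs, 1, the real one, called 11927 genes on average and the highest other 8644, with 2 pairs exchanged. The other exchanges likewise mix the treatments, so their counts do not measure false calls either. The number of lists past the threshold on average, 14, was reached by 14 of the 100 groupings, with 15 the highest other, so chance is not excluded for that number at the preset correlation. Apart from the real one, these groupings exchanged 2 to 6 of the 15 pairs. Much of a stimulus effect stays in such groupings, so this tally does not measure chance either. Of 100 orders of the times, 1, the real one, reached 4 genes for the difference of trends (highest other 0), 152 for the mock trend (highest other 2) and 214 for the stimulus trend (highest other 0). The 3 lists that differed in trend were reached by 67 of the 100, with 8 the highest other, so chance is not excluded for that number. For the interaction, a count of 0 is reached by all 100 by construction (highest other 1), which decides nothing, and the 93 genes with a replicate block were not compared with other orders.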

How the results depend on the processing

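Fits without the identical mock libraries, within replicates 1 and 2, with a block within each treatment and on counts summed over times were chosen after the data were seen. No named gene, and no list past the threshold, changed direction under any alternative run. The mRNA decay list, far from the threshold for the difference of trends, went from lower to higher with a replicate block (adjusted p = 0.973 and 0.895). The balance of higher and lower genes turned under some alternatives on average, at 7 to 10 h and for the trends. Examples are 6765 higher and 6785 lower on average in replicates 1 and 2 within a fit of all libraries, 1755 higher and 1862 lower at 7 h without organelle, rRNA and tRNA loci, 1966 and 2049 at 10 h with DESeq2 size factors, and 410 rising and 397 falling in mock with a replicate block. The cause of the other changes was not tested unless fewer samples are named. Of the counts and correlations, 279 stayed within set bounds and 134 did not (93 planned, 41 added later). The bound was a factor of 1.5 for counts, and any gene passing where the main count was 0. For the mean correlation between times it was the SD across pairs of times. The values of named genes lost their call 206 times and single lists 39 times. With a replicate block, the numbers of genes from 6 to 10 h were 6395, 7970, 6977, 7818 and 8318, the interaction gave 93, the difference of trends 262, the mock trend 807, the stimulus trend 1342, and 1 list differed in trend. With only the 6 libraries of each time they were 278, 1695, 713, 1449 and 1867. Without both identical libraries the difference of trends gave 94, the mock trend 285, and the correlation between times 0.80. With a block added there, the values were 4294, 5821, 7011, 7845 and 8321 by time, 171, 701, 1254 and 1419 for the interaction and the trends in the same order, and 0.807. In replicates 1 and 2 only, they were 6259, 8002, 7374, 7945 and 8260, then 596, 1624, 4803 and 3495, and 0.778. With a block as well, they were 6391, 8041, 7466, 8031 and 8317, then 604, 1665, 4879 and 3599, 5 lists, and 0.779. A block within each treatment gave 194, 797, 2887 and 3190, and 1 list. Sums over times gave 1824 genes on average and 3653 with a replicate block. DESeq2 gave 15 genes for the interaction and 82, 349 and 472 for the trends. Without a filter on low counts the difference of trends gave 1, the mock trend 100 and the correlation 0.517. Without the 6 h libraries the trends gave 0, 13 and 4 genes and 5 lists, without 10 h 0, 14 and 12, from 10 h minus 6 h 0, 36 and 78, and with a straight line 29, 244 and 397. With an estimated correlation 5 lists passed on average and 0 for the difference of trends.

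Leaving out 1 library gave ranges of 851 to 1995 genes at 6 h, 2240 to 3170 at 7 h, 1575 to 2310 at 8 h, 2103 to 2650 at 9 h and 2566 to 3193 at 10 h, each lowest without replicate 3 of the stimulus at that time. At 6 h the count was also 1017, 1173 and 1340 without mock replicates 1, 2 and 3, and at 7 h 2324 without mock replicate 2. The average ran from 11487 to 12070 genes with 14 lists throughout (14 to 14), and the interaction from 0 to 0. The difference of trends ran from 1 to 50, with 50, 20, 8 and 7 without stimulus 10 h replicate 3, mock 7 h replicate 3, stimulus 7 h replicate 3 and mock 10 h replicate 2, and 1 without each of 15 other libraries. The mock trend ran from 52 to 232, with 52 and 70 without mock 10 h replicates 1 and 2, 64 and 68 without mock 6 h replicates 1 and 2, 100 without mock 7 h replicate 1 and 232 without mock 9 h replicate 3. The stimulus trend ran from 55 to 255, with 74 and 55 without stimulus 10 h replicates 1 and 2, 82, 106 and 89 without stimulus 6 h replicates 1, 2 and 3 and 128 without stimulus 9 h replicate 2. Lists that differed in trend ran from 1 to 6, with 1 without stimulus 6 h replicate 1 or 2 or stimulus 10 h replicate 3, and 5 or 6 without each of 13 others. Depth limits low genes: the lowest library held 9541251 counts on nuclear loci other than rRNA and tRNA.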

Other observations

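The replicate sets differed in mock leaves before any stimulus effect, in a comparison chosen after the data were seen. FSD1, an iron superoxide dismutase, was 8.58 ± 0.23 higher on the log2 scale in replicate 3 (SE, 5 columns, 4 of them distinct, against 10 libraries, edgeR), MIR398b 8.97 ± 0.34, MIR408 8.33 ± 0.34 and YSL2 4.63 ± 0.23. Genes named here were chosen after their values were seen. Their SEs take the times of 1 replicate number as separate libraries, so they do not measure spread between independent replicate sets. The type-A response regulators ARR6 and ARR4 were 4.61 ± 0.44 and 3.70 ± 0.18 higher, and responded less to the stimulus there, at 3.35 against 7.05 and 2.01 against 5.03. THI2.1 was lower by -7.10 ± 0.85.

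A candidate explanation for part of this is a lower copper supply in replicate 3, since FSD1, MIR398b and MIR408 are known to rise at low copper. The hypothesis was tested on further copper-related genes, listed with their directions before their values were looked at. All 8 that could be tested differed in the listed direction, with a median signed log2 difference of 2.61. In mock 13786 of 21052 genes differed between the sets, so a call alone says little beside direction and size. Whether these 8 genes vary independently of the genes already seen, microRNA genes among them, was not tested. Their number is therefore not a count of independent tests of low copper. COPT2, a copper transporter, was 5.43 ± 0.34 higher, CCH 3.14 ± 0.11 higher, and the copper superoxide dismutase genes CSD1 and CSD2 stood at -2.44 ± 0.20 and -2.69 ± 0.16. Unequal removal of rRNA and organelle RNA was examined by leaving out organelle, rRNA and tRNA loci. Of the 13604 nuclear genes that differed, 98.1% were still called, so the calls did not depend on counting those loci. This cannot decide on unequal removal, since TMM already allows for such shares and dropping loci would not undo effects on nuclear RNA. The copper hypothesis covers few of the genes that differed, and the labels name no copper treatment.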
